A study of Mus musculus with 6 samples.

How the data were processed

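Gene expression was measured by RNA sequencing in germinal centre (GC) B cells of mice, the B cells that divide and mutate their antibody genes during an immune response. The labels divide 6 libraries into 3 with the LDHA gene intact (WT) and 3 without it (KO), numbered 1 to 3 in each group. Total RNA was purified with Trizol and libraries were made with a SMARTER mRNA-seq kit, per the labels' protocols. The labels do not say that the samples came from separate animals. The p-values set the difference between groups against the spread of these samples within groups, which need not be the spread between animals.

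The deposited table holds whole-number fragment counts per gene, not normalized, for 55487 genes, per the file headers and the values. The counts were made by featureCounts 2.0.1 on exons grouped by gene, with the GENCODE vM25 primary assembly annotation, per the file headers. The command counted fragments and kept every alignment of multi-mapping reads, set no strand option and did not drop marked duplicates, per the file headers. STAR 2.7.7a and GATK 4.1.9.0 and the mm10 build are named without their roles, per the submitters' processing notes. Because every alignment of a multi-mapping read was counted, a gene and a near-identical copy share counts. This concerns the mitochondrial genes, which have nuclear copies, and the ribosomal protein, histone, zinc finger and Ifi200 families. Ldha has pseudogenes of similar sequence, so reads shared with them count for Ldha too. Without strand, reads of overlapping antisense genes cannot be told apart.

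Columns were matched to samples through the number in each sample's description. Coordinates are those of the deposited table (mm10, 1-based). Symbols came from a gene name table and the GENCODE M21 annotation, matched by Ensembl identifier. They were found for 55227 genes, and the 260 others held 0.0720% of all counts. Total counts per library ran from 32673837 to 56860073, a 1.74-fold range, and the totals did not separate the groups. The depth sets the precision of genes with few counts, and counting error is only part of the spread between libraries.

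Genes were kept by the default filterByExpr rule of edgeR 4.0.16 in R 4.3.3, which left 17070. Counts were scaled by TMM and tested with the edgeR quasi-likelihood F test with robust estimation, two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values are counts relative to library size as edgeR gives them, scaled by the same factors and given as mean ± SD over 3 libraries. Log2 fold changes are KO over WT with their standard errors (SE). Fixed gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Of the 42 lists, 41 had at least 5 kept members and were tested, with p-values adjusted over the lists. Each list was also tested with a correlation estimated from the data and with fry, whose directional p asks whether the genes of a list move one way on balance. Groups, tests, lists and the rule for named genes were fixed before the data were examined.

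The rule names 18 genes of LDHA biology and GC B cell identity, of which Ldhc was below the filter with at most 1 count in any library and 1 other is not reported here. It adds the 10 genes with the smallest adjusted p in each direction whose WT and KO libraries do not overlap, leaving out immunoglobulin and T cell receptor segments and genes with Gm, Rik or pseudogene names. It adds the 4 members with the smallest p in the direction of each list called by camera, and the 2 most abundant members of each list for other cell types, sex-linked genes or RNA quality.

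A dependence of fold changes on the GC content of genes was seen in the data, and a correction for it was chosen after that. GC content was the mean over the basic GENCODE M21 transcripts of each gene, and a value was found for 99.7% of the tested genes. For each library a loess curve (span 0.3) of centred log2 CPM on GC content entered the edgeR fit as an offset, over 17015 genes. For lists, the curve was instead subtracted from log2 CPM before camera. List medians, with or without offsets, are medians of the differences between group means of log2 CPM. Values from either correction are called GC-offset values. Such offsets also remove any real difference that follows GC content.

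The procedure was tested on simulated data drawn from the libraries' means, sizes and dispersions for the KO and WT comparison, with 200 genes changed. The changed genes were picked among those with a mean of at least 1 CPM. Without a GC trend, over 16636 genes, it recovered 16.4% of genes changed by a fold of 1.5, 70.1% at a fold of 2 and 89.4% at a fold of 4. It called 11 unchanged genes, which were 8.59% of its calls. With the measured GC trend added and no offsets, over 16674 genes, it called 6623 unchanged genes, which were 97.8% of its calls. With offsets, over 16620 genes, it called 13 unchanged genes, which were 10% of its calls. It then recovered 13.4%, 71.6% and 90.9% of genes changed by those folds. In simulations with 3 lists moved, camera called all 3 each time. It called 5 lists with no moved member when the GC trend was present and uncorrected, and 0 such lists with offsets or without the trend. Genes were drawn independently, so these simulations do not show how camera behaves when the genes of a list vary together. The added trend came from the same loess method as the offsets, so they were bound to remove most of it.

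Alternatives covered the test (DESeq2 1.42.0, limma-voom, non-robust estimation, a minimum fold, a looser threshold), scaling, filters, removal of immunoglobulin, mitochondrial and haemoglobin genes, a block for replicate number, and leaving out each library. Restriction to protein-coding genes was added after the data were seen. For lists, camera on ranks was also run. No sample was left out of the main comparison.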

Results

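RNA of LDHA-sufficient and LDHA-deficient mouse GC B cells was compared in 3 WT and 3 KO libraries. LDHA is the lactate dehydrogenase subunit that interconverts pyruvate and lactate at the end of glycolysis. Total counts were 33131711, 56860073 and 32673837 in WT replicates 1 to 3 and 38969337, 47517179 and 56781303 in KO replicates 1 to 3. Pairs of libraries of the same group correlated across genes at 0.972 to 0.981 on the log2 CPM scale. Their counts differed by more than sampling noise in every such pair, with a chi-square per degree of freedom of at least 26.0.

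Ldha, the targeted gene, was lower in every KO library than in every WT library. Its level was 687 ± 90.5 CPM in WT and 259 ± 21.2 CPM in KO (SD, 3 libraries each). That is a log2 fold change of -1.41 ± 0.13 (SE), with an edgeR adjusted p of 4.96e-05. KO libraries kept 37.8% of the WT level. The gene (ENSMUSG00000063229.15) lies on chromosome 7 from 46841475 to 46855627 on the plus strand of mm10. Counts cover all annotated exons, and the labels do not say which part of the gene was removed, so the remaining count does not measure functional transcript. With GC offsets the log2 fold change was -1.27 ± 0.12 and the edgeR adjusted p was 0.000549.

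**Figure D1:**
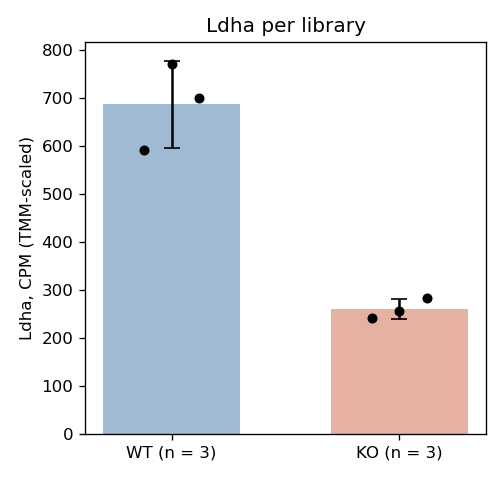
Ldha in CPM (TMM-scaled, vertical axis) in the WT and KO groups, where bars are means, error bars are SD and points are the 3 libraries of each group. The KO libraries lie between 241 and 282 CPM and the WT libraries between 591 and 770 CPM.

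Other genes of lactate and pyruvate handling differed in direction without GC offsets. Slc16a3, a lactate exporter (MCT4), fell from 30.5 ± 14.1 CPM in WT to 8.04 ± 1.02 CPM in KO, a log2 fold change of -1.93 ± 0.31 (edgeR adjusted p = 0.000876) and -1.16 ± 0.28 with GC offsets (edgeR adjusted p = 0.0253). Slc16a1, which encodes the lactate transporter MCT1, stood at 50.7 ± 9.45 and 62.9 ± 10.5 CPM (edgeR adjusted p = 0.168). With GC offsets its log2 fold change turned to -0.58 ± 0.16 (edgeR adjusted p = 0.0464). Ldhb, the other main lactate dehydrogenase subunit, was near 1 CPM in both groups, at 1.07 ± 0.0550 in WT and 0.598 ± 0.170 in KO (edgeR adjusted p = 0.122), and stood at -0.56 ± 0.41 with GC offsets (edgeR adjusted p = 0.430). The list of 21 measured genes for pyruvate and lactate handling had 4 that rose and 6 that fell. Adjusted over the list alone, 5 rose and 6 fell. The list was not called by camera (adjusted p = 0.946). With GC offsets 0 of its genes were higher and 4 lower by edgeR. Camera then called the list lower, with a median of -0.21 (adjusted p = 0.0328). That call was lost at adjusted p = 0.995 with an estimated correlation.

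Across the transcriptome, 7778 of 17070 tested genes differed between KO and WT by edgeR, with 4102 higher and 3676 lower in KO. Of these, 2004 were higher and 1081 lower by at least a fold of 2. In 7571 of them the WT and KO libraries did not overlap. Over all tested genes 55.6% had groups that did not overlap, against 10% by chance for this design. The changed genes include 1777 immunoglobulin or T cell receptor segments, Gm, Rik or pseudogene names, which are not named here.

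The fold changes followed the GC content of the genes. Among 291 genes under 38% GC, 231 rose in KO and 1 fell, with a median log2 fold change of 1.92. Among 1599 genes above 58% GC, 1097 fell and 4 rose, with a median of -0.94. Across protein-coding genes, which are not independent replicates, Spearman's rho between fold change and GC content was -0.80, and a curve on GC content held 59.8% of the variance of fold changes. The rho between a library's centred expression and GC content was 0.613 to 0.630 in the WT libraries and -0.665 to -0.606 in the KO libraries.

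With GC offsets, 1995 genes differed by edgeR, 876 higher and 1119 lower in KO. Of the 7778 genes, 1336 were called in the same direction with GC offsets and 145 in the opposite direction, and 514 genes were called only with offsets.

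**Figure D2:**
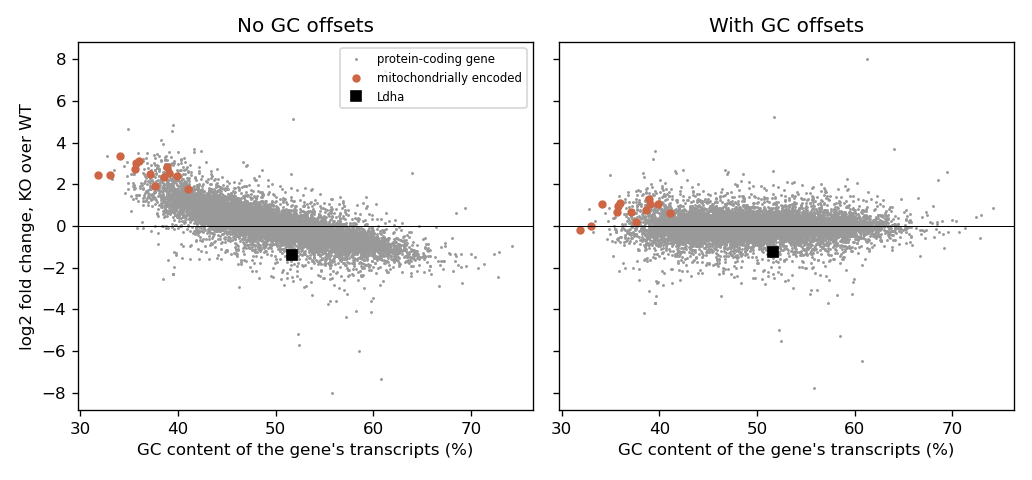
Log2 fold change, KO over WT (vertical axis), against the GC content in percent of each protein-coding gene's transcripts (horizontal axis), without GC offsets on the left and with them on the right. Grey points are genes, orange points are mitochondrially encoded genes and the black square is Ldha, which stands at -1.41 on the left and -1.27 on the right.

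Mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and ATP synthase, were higher in KO as a group. All 13 rose by edgeR, and all 13 did so adjusted over the list alone, with a median log2 fold change of 2.48 (camera adjusted p = 1.45e-10, and adjusted p = 0.904 with an estimated correlation). Cytochrome oxidase subunit mt-Co3 went from 242 ± 22.9 CPM in WT to 1703 ± 74.2 CPM in KO, and mt-Atp6 from 206 ± 32.1 to 1781 ± 37.4 CPM. The complex I subunits mt-Nd4 and mt-Nd5 were higher by folds of 6.73 and 5.57. These mRNAs took 0.130% ± 0.0139 of all counts in WT and 0.833% ± 0.0164 in KO (SD, 3 libraries each). The exact two-sided permutation test of that share gave p = 0.1, the smallest this design allows. Their median GC content was 37.1%, at the low end of all genes, and with GC offsets 10 of the 13 remained higher, with a median of 0.78 (camera adjusted p = 1.60e-06, and adjusted p = 0.995 with an estimated correlation). The log2 fold changes of mt-Co3, mt-Atp6, mt-Nd4 and mt-Nd5 with GC offsets were 1.28, 1.11, 0.69 and 0.66.

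Nuclear genes of respiration were not called as a group. Of 78 nuclear OXPHOS subunits, 16 rose, 35 fell and 27 did not pass the test. Adjusted over the list alone, 16 rose and 36 fell (camera adjusted p = 0.250), and with GC offsets 10 were higher and 10 lower. Of 78 mitochondrial ribosomal protein genes, 14 rose and 28 fell, and 15 rose and 28 fell adjusted over the list alone (camera adjusted p = 0.187), and with GC offsets 1 was higher and 10 lower (camera adjusted p = 0.123). Of 21 TCA cycle genes, 5 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.946), and with GC offsets 0 differed by edgeR.

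Glycolysis genes were lower in KO before GC offsets. Of 23, 11 fell, 2 rose and 10 did not pass, with the same counts adjusted over the list alone and a median of -0.33 (camera adjusted p = 0.0427, and adjusted p = 0.999 with an estimated correlation). The kinase Pfkl fell from 182 ± 20.8 to 102 ± 11.4 CPM, pyruvate kinase Pkm from 1938 ± 336 to 1159 ± 35.4 CPM, and enolase Eno1 from 1565 ± 219 to 1034 ± 26.8 CPM. The glucose transporter Slc2a1 fell by 0.64 on the log2 scale (SE 0.15, edgeR adjusted p = 0.00565), and hexokinase Hk2 stood at -0.18 ± 0.21 (edgeR adjusted p = 0.527). With GC offsets Pfkl, Pkm, Eno1 and Slc2a1 stood at -0.17, -0.08, -0.11 and -0.26 and none of these passed the edgeR threshold, and Hk2 stood at 0.24 ± 0.21. Of the 23, 0 were then lower and 1 higher, the median was -0.07 and the list was not called (camera adjusted p = 0.957). Without offsets, the adjusted p of the list was 0.0588 by fry.

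Genes of the HIF-1 response, which follows low oxygen, were not called as a list. Of 28, 3 rose and 8 fell, and 3 rose and 7 fell adjusted over the list alone (camera adjusted p = 0.717), and with GC offsets 1 was higher and 4 lower (camera adjusted p = 0.479). Hif1a, which encodes the oxygen-regulated subunit, was higher in KO by 0.91 ± 0.13 on the log2 scale (edgeR adjusted p = 0.000534) and stood at -0.06 ± 0.12 with GC offsets (edgeR adjusted p = 0.781). Pdk1, the kinase that restrains pyruvate dehydrogenase, stood at 0.11 ± 0.15 (edgeR adjusted p = 0.594) and -0.34 ± 0.14 with GC offsets.

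The integrated stress response genes that ATF4 drives fell in part. Of 28, 12 fell and 2 rose, and 13 fell and 3 rose adjusted over the list alone, with a median of -0.40 (camera adjusted p = 0.0427, and adjusted p = 0.999 with an estimated correlation). Cebpb fell from 95.5 ± 33.2 to 22.7 ± 5.45 CPM and Shmt2, a mitochondrial serine enzyme, from 423 ± 40.2 to 237 ± 10.1 CPM. Slc3a2, an amino acid transporter chain, fell by 0.72 on the log2 scale and Ddit4 by 0.90. With GC offsets the list median was -0.02 (camera adjusted p = 0.904), and of these 4 genes Slc3a2 was still lower, at -0.38 ± 0.10 (edgeR adjusted p = 0.0398). Cebpb, Shmt2 and Ddit4 then stood at -0.60, -0.15 and -0.17, not past the threshold.

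Mitotic genes were higher in KO before GC offsets. Of 43 G2/M genes, 25 rose, 4 fell and 14 did not pass, and 26 rose and 4 fell adjusted over the list alone, with a median of 0.60 (camera adjusted p = 0.000899, and adjusted p = 0.999 with an estimated correlation). Kif20b, a mitotic kinesin, rose from 16.7 ± 1.69 to 77.2 ± 17.0 CPM. Hmmr, Nuf2 and Smc4 were higher by folds of 2.66, 2.35 and 2.34. Mki67, a proliferation marker, rose by 1.01 ± 0.15 on the log2 scale, and by 0.59 ± 0.14 with GC offsets (edgeR adjusted p = 0.0278). With GC offsets 5 of the 43 were higher and 0 lower by edgeR, and the list was not called, with a median of 0.14 (camera adjusted p = 0.123). Kif20b was then still higher, at 0.74 ± 0.16 (edgeR adjusted p = 0.0164), while Hmmr, Nuf2 and Smc4 stood at 0.35, 0.36 and -0.20, not past the threshold. Of 43 genes of G1/S and DNA replication, 13 rose and 12 fell, and 14 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.780), and with GC offsets 3 were higher and 2 lower.

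Counts of replication-dependent histone genes, whose mRNAs accumulate during DNA synthesis, were lower in KO. Of 30, 27 fell and 0 rose by edgeR, with the same counts adjusted over the list alone and a median of -0.998 (camera adjusted p = 1.07e-08, and adjusted p = 0.999 with an estimated correlation). Hist1h1e fell from 29.1 ± 5.77 to 10.5 ± 1.26 CPM and Hist1h2ae from 114 ± 31.6 to 36.3 ± 3.26 CPM. The log2 fold changes of Hist1h2ag and Hist1h2ad were -1.31 and -1.37. With GC offsets 10 of 30 were lower and the median was -0.38 (camera adjusted p = 0.000248, and adjusted p = 0.995 with an estimated correlation). Hist1h1e and Hist1h2ae then stood at -1.38 ± 0.18 and -1.26 ± 0.18, and Hist1h2ag and Hist1h2ad at -0.03 ± 0.13 and -0.48 ± 0.15, the latter pair not past the threshold. Histone genes are near-identical and share reads. Libraries were made with an mRNA-seq kit, and whether it captures histone transcripts in full was not tested, so these counts may not follow their level.

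Immediate early genes, which cells switch on within minutes of stimulation, were lower in KO. Of 23, 15 fell, 1 rose and 7 did not pass, and 15 fell and 2 rose adjusted over the list alone, with a median of -0.81 (camera adjusted p = 0.000394, and adjusted p = 0.904 with an estimated correlation). The AP-1 genes Jun, Junb and Jund fell, with log2 fold changes of -1.72, -1.68 and -1.68, and Ier5 fell from 268 ± 18.2 to 97.1 ± 18.8 CPM. With GC offsets 6 of the 23 were lower and the median was -0.38 (camera adjusted p = 0.00744, and adjusted p = 0.995 with an estimated correlation). Ier5 and Jun then stood at -1.27 ± 0.14 and -1.20 ± 0.17, Junb at -0.52 ± 0.12 and Jund at -0.23 ± 0.10 (edgeR adjusted p = 0.192).

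Interferon response genes were higher in KO. Of 41, 20 rose, 1 fell and 20 did not pass, and 22 rose and 2 fell adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.00166, and adjusted p = 0.999 with an estimated correlation). Ifi209 rose from 48.5 ± 9.85 to 271 ± 9.78 CPM and Trim30a from 10.8 ± 2.32 to 40.7 ± 3.77 CPM. Herc6 and Ifit2 were higher by folds of 2.80 and 3.21. With GC offsets 6 of the 41 were higher, with a median of 0.32 (camera adjusted p = 0.00530, and adjusted p = 0.995 with an estimated correlation). Ifi209 and Trim30a then stood at 1.02 ± 0.14 and 0.69 ± 0.17, and Herc6 and Ifit2 at 0.04 ± 0.16 and 0.67 ± 0.22, not past the threshold. The list without offsets had an adjusted p of 0.0550 by fry.

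The antigen presentation genes were lower in KO before GC offsets. Of 23, 11 fell and 3 rose, and 12 fell and 3 rose adjusted over the list alone, with a median of -0.37 (camera adjusted p = 0.0331, and adjusted p = 0.999 with an estimated correlation). The 4 with the smallest p belong to the class I pathway: the peptide transporter genes Tap2 and Tap1, the chaperone Tapbp and the class I heavy chain H2-D1. Tap2 fell from 487 ± 26.5 to 226 ± 1.49 CPM and H2-D1 from 6315 ± 296 to 3581 ± 560 CPM. Tap1 fell by 0.77 and Tapbp by 0.60 on the log2 scale. With GC offsets Tap2 stood at -0.45 ± 0.09 (edgeR adjusted p = 0.0131), Tap1, Tapbp and H2-D1 at -0.09, 0.04 and -0.27, not past the threshold, and the list was not called (camera adjusted p = 0.939). For the list without offsets the adjusted p was 0.0584 by fry.

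**Figure D3:**
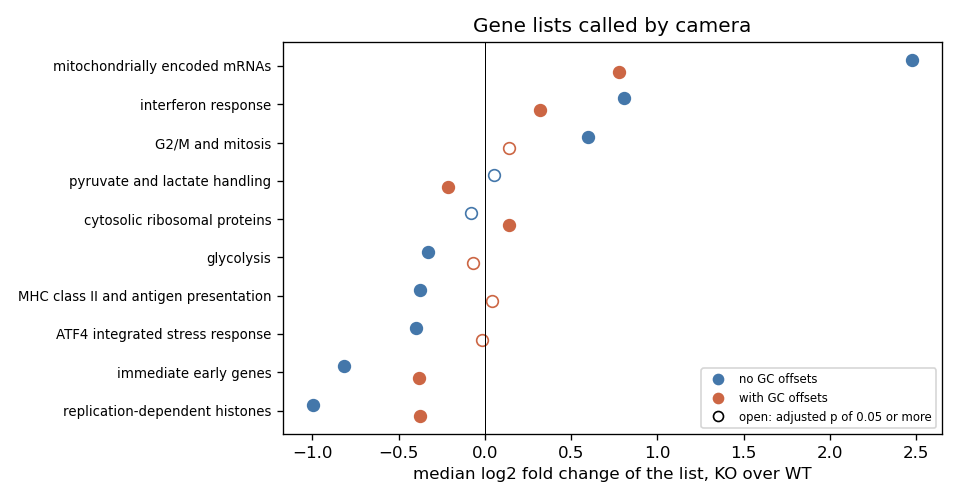
Median log2 fold change, KO over WT (horizontal axis), of each gene list that camera called without GC offsets (blue) or with them (orange). Filled points have an adjusted p under 0.05 with the preset correlation. The mitochondrially encoded mRNAs stand at 2.48 without offsets and 0.78 with them.

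Genes of GC B cell identity moved in both directions. Of 31, 9 rose and 12 fell, and 9 rose and 13 fell adjusted over the list alone (camera adjusted p = 0.780), and with GC offsets 3 were higher and 6 lower. Bcl6, the repressor that sets the GC program, was 299 ± 28.5 CPM in WT and 215 ± 22.1 CPM in KO (edgeR adjusted p = 0.00897). With GC offsets its log2 fold change was -0.37 ± 0.12 (edgeR adjusted p = 0.0671). Myc fell by 0.79 on the log2 scale (SE 0.14, edgeR adjusted p = 0.00115) and stood at -0.30 ± 0.13 with GC offsets (edgeR adjusted p = 0.182). Fas rose by 0.80 ± 0.14 (edgeR adjusted p = 0.00114) and stood at -0.02 ± 0.15 with GC offsets (edgeR adjusted p = 0.946). Prdm1, the plasma cell regulator, stood at 0.32 ± 0.32 (edgeR adjusted p = 0.447) and 0.16 ± 0.31 with GC offsets.

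Markers of the light zone, where GC B cells are selected, were more often lower than higher in KO. Of 31 light zone and activation genes, 7 rose and 18 fell, and 8 rose and 18 fell adjusted over the list alone, with a median of -0.40. Camera did not call the list (adjusted p = 0.250) and fry called it lower (adjusted p = 0.0401). With GC offsets 4 were higher and 4 lower, with a median of -0.08 (camera adjusted p = 0.760). Cd83 rose from 486 ± 45.6 to 660 ± 68.5 CPM (edgeR adjusted p = 0.0128) and stood at 0.59 ± 0.12 with GC offsets (edgeR adjusted p = 0.0122). Cd86 rose by 1.24 ± 0.17 on the log2 scale (edgeR adjusted p = 0.000315) and stood at 0.41 ± 0.17 with GC offsets (edgeR adjusted p = 0.160). Of 20 dark zone genes, 8 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.684), and with GC offsets 5 were higher and 2 lower. The dark zone receptor Cxcr4 rose by 0.42 ± 0.13 (edgeR adjusted p = 0.0269) and stood at -0.05 ± 0.14 with GC offsets. The call for Cxcr4 was lost on leaving out WT replicate 2, WT replicate 3, KO replicate 1 or KO replicate 3, with edgeR adjusted p up to 0.0823, and with upper-quartile scaling (0.0604).

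The genes with the smallest adjusted p higher in KO were, beside 7 mitochondrial genes, Ube2v2, Zfp992 and Sept7. Ube2v2, a ubiquitin-conjugating enzyme variant, rose from 18.3 ± 1.30 to 105 ± 3.12 CPM and stood at 0.72 ± 0.11 with GC offsets (edgeR adjusted p = 0.00427). The zinc finger gene Zfp992 rose from 3.81 ± 0.251 to 30.8 ± 2.25 CPM and Sept7, a septin, from 99.8 ± 6.44 to 418 ± 21.1 CPM. With GC offsets they stood at 1.14 ± 0.15 and 0.61 ± 0.10 (edgeR adjusted p = 0.00165 and 0.00647). Among those lower in KO with the smallest adjusted p, Cdk13, a transcriptional kinase, fell from 172 ± 13.2 to 67.8 ± 5.24 CPM. Cdk13 stood at -1.83 ± 0.12 with GC offsets (edgeR adjusted p = 0.000226). The glycosyltransferase gene B3gnt2 fell from 19.4 ± 1.97 to 5.43 ± 0.117 CPM and stood at -2.26 ± 0.16 with GC offsets (edgeR adjusted p = 0.000226). Pou2f2, a B cell octamer factor, fell by 1.27 on the log2 scale and stood at -0.41 ± 0.09 with GC offsets, and Nfkbib fell by 1.25 and stood at -0.36 ± 0.10. Tysnd1, Abhd8, Ssbp4 and the ribosomal RNA model CT010467.1 fell, with log2 fold changes of -1.61, -1.34, -1.59 and -1.70. With GC offsets these 4 stood at -0.27, -0.21, -0.28 and -0.16, and none passed the edgeR threshold, with adjusted p of 0.0977, 0.248, 0.157 and 0.445.

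Markers of other cells and of RNA quality were not called. Of 8 such lists 0 passed camera, 0 passed fry and 0 had an unadjusted p under 0.05 by either, and the smallest camera adjusted p was 0.437. Single members did differ. Apoe, abundant in macrophages, fell from 1326 ± 242 to 537 ± 77.0 CPM, and Lyz2 stood at 320 ± 114 and 261 ± 37.2 CPM. Lck, a T cell kinase, was 257 ± 70.3 and 150 ± 32.9 CPM, while Trbc2 was 13.1 ± 1.46 and 11.8 ± 1.86 CPM. The neutrophil genes Ltf and Ngp were at 180 ± 65.7 and 145 ± 55.0 CPM in WT, and at 110 ± 58.2 and 126 ± 59.1 CPM in KO. The lineage factor Tbx21 fell by 1.11 on the log2 scale and Prf1 stood at -0.57 ± 0.47. Tcf4 stood at -0.13 ± 0.09 and Cst3 at -0.55 ± 0.15. The haemoglobin genes Hbb-bt and Hbb-bs stood at -0.40 ± 0.37 and -0.24 ± 0.41. Pecam1 rose by 0.54 ± 0.19 and Mfge8 fell by 0.74 on the log2 scale. The nuclear RNA Malat1 was 137 ± 37.6 CPM in WT and 196 ± 8.80 CPM in KO, and its log2 fold change turned from 0.51 ± 0.18 to -0.61 ± 0.17 with GC offsets. Lars2 stood at 0.03 ± 0.11. Of the members named here and called without offsets, only Malat1 was past the threshold with GC offsets. Apoe, Lck, Tbx21, Cst3, Pecam1 and Mfge8 then stood at -0.49, -0.35, -0.23, 0.13, 0.52 and -0.04, with edgeR adjusted p of 0.0511, 0.308, 0.580, 0.609, 0.0994 and 0.942. Xist was present in all 6 libraries and higher in KO, at 41.4 ± 6.73 against 11.8 ± 3.08 CPM, and its log2 fold change stood at 0.70 ± 0.20 with GC offsets (edgeR adjusted p = 0.0504). The 4 Y-linked genes had at most 4 counts in any library.

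Camera called 8 of 41 lists, 3 higher and 5 lower in KO. With GC offsets it called 6, of which 4 were among the 8: mitochondrially encoded mRNAs, replication-dependent histones, immediate early genes and interferon response. With an estimated correlation 0 lists passed and 2 had an unadjusted p under 0.05. The mitochondrially encoded mRNAs, all 13 of which rose, did not pass camera with it (adjusted p = 0.904). The simulations did not check the power of that test, so its high p-values do not show that a list is unchanged. Fry, run without GC offsets only, called 8 lists, of which 5 were among those of camera. It did not call glycolysis, interferon response and antigen presentation, and it called apoptosis regulators, light zone genes and class switch machinery instead. The medians of apoptosis regulators and class switch machinery were 0.27 and 0.24 without GC offsets. With offsets they were 0.02 and 0.07, and camera did not call these lists (adjusted p = 0.740 and 0.901). Other ways of splitting the same 6 libraries gave 6 to 13 lists by camera. The median, mean and test of a list differed in sign in 11 lists, those for pyruvate and lactate handling, pentose phosphate, cytosolic ribosomal proteins, GC B cell identity, naive follicular B cells, B cell receptor signalling, unfolded proteins, T cells, dendritic cells, NK cells and stroma. None of these 11 was called by camera without GC offsets.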

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

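GC offsets and the restriction to protein-coding genes were chosen after the data were seen. Ldha was lower in KO past the threshold in every alternative, with log2 fold changes from -1.50 to -1.27 and adjusted p up to 0.000598. The count of changed genes stayed within a factor of 1.5 of 7778 except with GC offsets (1995, with 876 higher and 1119 lower) and in a test against a fold of 1.5 (2898, with 1853 higher and 1045 lower, by construction stricter). Leaving out each library gave 6214 to 7312 changed genes, 3443 to 3980 higher and 2771 to 3398 lower. The share of calls higher in KO was 47.9% to 57.9% over the scalings, against 52.7%.

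Of 41 lists, 8 were called (3 higher, 5 lower). An estimated correlation left 0 (0 higher, 0 lower), with GC offsets too. Fry kept 5 of the 8 and called 3 others. Library size alone left 3 lower. GC offsets gave 3 lower, of which histones and immediate early genes were among the 5 and pyruvate and lactate handling was a new call. Protein-coding genes only gave 5, with 2 lower, ending the calls for glycolysis, ATF4 and antigen presentation. Leaving out each library gave 5 to 9 lists and 2 to 6 lower. Library size alone ended the calls for glycolysis and ATF4 (adjusted p = 0.0527 for both), and a filter at 1 CPM in 3 libraries ended that for glycolysis (0.0592). The call for glycolysis also ended without WT replicate 2, KO replicate 1 or KO replicate 2. ATF4 ended without WT replicate 3, KO replicate 2 or KO replicate 3, and antigen presentation without WT replicate 1, KO replicate 2 or KO replicate 3. Without KO replicate 2, 5 lists with 2 lower were left, and without KO replicate 3 there were 3 lower. The cause was not tested. With GC offsets the test of glycolysis turned upward at a median of -0.0711, with either correlation.

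Directions turned with GC offsets for Hk2 (0.24), Pdk1 (-0.34), Hif1a (-0.0638), Fas (-0.0224), Cxcr4 (-0.0543), Slc16a1 (-0.58), Smc4 (-0.20), Tapbp (0.0408), Cst3 (0.13) and Malat1 (-0.61), and 29 other named genes lost their call. Upper-quartile scaling turned Lars2 (-0.0303) and ended the calls for Cxcr4, Pecam1 and Malat1 (adjusted p 0.0604, 0.0613 and 0.0747). Leaving out a library turned the direction of genes that were not called: Lars2 (-0.00420 without WT replicate 1 to 0.134), Prf1 (-0.909 to 0.202, higher without WT replicate 1), Lyz2 (-0.447 to 0.0303, higher without WT replicate 2), Ngp (-0.598 to 0.0818, higher without WT replicate 2 or KO replicate 1), Hbb-bt (-0.894 to 0.00633) and Hbb-bs (-0.744 to 0.198), both higher without KO replicate 2. Lars2 was also below 0 without KO replicate 2. Pecam1 and Malat1 kept their call only without WT replicate 1. Mfge8 lost its call without WT replicate 2 or 3 or KO replicate 2 or 3, Cst3 without WT replicate 3 or KO replicate 2 or 3, and Lck without KO replicate 2. Slc16a1 passed without KO replicate 1 and Ltf without KO replicate 2.

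A replicate block gave 6974 changed genes and 8 lists, ended the call for Cxcr4 (adjusted p = 0.0615) and added a call for Ltf (0.00577). Deviations of same-numbered libraries correlated at -7.19e-05, -0.00829 and -0.0122, so the numbers were not taken to pair samples. In simulations with 200 changed genes, the test recovered 16.4% of those changed by a fold of 1.5. In the main fit far more genes passed, which loosens the cut on unadjusted p, so that share does not carry over. How many small changes the main fit misses at this depth and number of libraries was not measured.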

Other observations

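The tests of library size, and of the GC trend for mitochondrial and interferon genes, were chosen after the results were seen, as was the look at zinc finger genes. Among protein-coding genes named Zfp, many of which encode DNA-binding repressors, 184 of 340 rose in KO and 52 fell by edgeR. Their median GC content was 44.9%, against 50.6% for protein-coding genes. With GC offsets 64 were higher and 12 lower, so that 84.2% of the called Zfp genes were higher, against 42.3% of the other called genes. The family was picked after its values were seen, so no p is given for this share. Members of this family share sequence, and reads mapping to several of them were counted for each. Cytosolic ribosomal protein genes split as well: of 79, 23 rose and 20 fell, and with GC offsets 18 were higher and 8 lower, a list camera then called higher (adjusted p = 0.0152, and 0.995 with an estimated correlation).

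Fold changes fell with GC content at a slope of -1.11 per 10 points of GC in protein-coding genes. A GC-dependent bias between the 2 sets of libraries should appear in other classes of gene too, and the slope was negative in all 5 tested, at -0.996 ± 0.0615 or steeper. Antisense genes and processed pseudogenes can take reads of protein-coding genes under this counting, so their slopes may partly repeat that trend, which was not measured. LincRNAs and immunoglobulin V segments gave -1.12 ± 0.0723 and -1.16 ± 0.212. Library size does not account for it: WT replicate 2 and KO replicate 3 have nearly equal totals, yet their slopes differ by 22.8 pooled SDs. The labels give no library batch, every KO library differs from every WT library in this respect, and a biological effect that follows GC content stays open and untested.

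Mitochondrially encoded mRNAs were higher in KO by a median of 2.48 on the log2 scale, and by 0.78 (SD 0.462 over 13 genes) with GC offsets. The GC trend may account for most of the difference. With offsets their median was above that of 99.84% of 10000 random lists of nuclear genes of matched GC content, whose central 95% ran from -0.51 to 0.43, while the bound set for excluding the trend lay higher. The bound set for the interferon list, also after the results were seen, was lower, and the mitochondrial median would pass it. Random lists for interferon were also not matched on GC content, so these lists were judged by different bounds and different comparisons. Random genes were drawn independently, while the 13 mRNAs may vary together, so the random range may be too narrow. Whether a remainder is separate from the trend cannot be told apart here at the bound set, and a genotype effect was not tested apart from the libraries.

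Interferon response genes were higher in KO by a median of 0.32 with GC offsets, with 32 of 41 positive. That was above 99.99% of 10000 random lists matched on mean expression. These lists were not matched on GC content, so the comparison does not decide whether the GC trend is the source. The list's median GC content was 46.7%, and with offsets genes at 46% to 50% GC had a median log2 fold change of 0.01. The offsets centre each range of GC content by construction, so that value is no separate check. The Ifi200 cluster on chromosome 1 is not the whole source, since the median was 0.30 without its 5 members. Random lists ignore that these genes vary together, so variation between libraries in a shared response stays open beside genotype. By camera with an estimated correlation and GC offsets the adjusted p was 0.995. That test passed 0 lists, the mitochondrial mRNAs included, so its result does not decide the question.

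For the gene count, 1 of 10 splits of the 6 libraries, the real one, gave as many as 7778 genes. The highest other count was 0 by edgeR and 0 by limma-voom, and at most 402 genes had an unadjusted edgeR p under 0.05. Every other split mixes the genotypes, so the genotype and GC difference widens the spread within groups and holds these counts down. The contrast with 7778 therefore says little by itself. For lists, 6 of the 10 splits gave at least 8, and the highest other count was 13. With 10 splits no share under 0.05 can be reached. Splits mixing the genotypes gave 6 to 13 lists by camera with the preset correlation. Each of them sets 2 libraries of a genotype against 1, so part of the genotype and GC difference stays in it, and the source of those calls was not tested.

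A further hypothesis was that a chromosome 7 segment carried along with the Ldha allele adds changed genes near Ldha. Within 10 Mb of Ldha 18 of 165 tested genes were called with GC offsets, against 1976 of 16849 elsewhere (Fisher's exact test, odds ratio 0.922, 95% interval 0.530 to 1.51), so no excess was seen there.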
